A study of Mus musculus with 4 samples.

How the data were processed

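Total RNA from mammary glands of 13-week-old Δ16HER2 transgenic female mice was labelled with Cy3 and hybridised to 4 one-colour Agilent mouse arrays, 2 from mice labelled wild type and 2 from mice labelled stathmin knockout, per the labels. The description field of each sample names EOC cells instead, which disagrees with the other labels, and it was not used. All 4 arrays lay on 1 slide and were scanned in 1 scan, per the file headers, so neither slide nor scan could be tested as a batch. The wild-type samples occupied the first positions of the slide and the knockout samples the others, so slide position and genotype cannot be told apart.

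The authors deposited the scanner's spot intensity files. Processed signal intensities were made by Agilent Feature Extraction, version 11.5.1.1 per the file headers and 10.7.3.1 per the submitters' processing notes, which subtracts the background and corrects spatial trends within each array. Nothing was done between arrays in these files. The authors also deposited a table of log2 values, which the series' design text ascribes to GeneSpring, with scale, centring and steps unstated. Against the scanner values, that table matched quantile-normalized log2 processed signals centred on each probe's median over the 4 arrays (Pearson r from 0.99997 across probes, median absolute difference at most 0.00031), so its scale, centring and direction were settled from the data. Its column medians were -0.018, 0.0183, 0.00626 and -0.00958 for WT 1, WT 2, knockout 1 and knockout 2.

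The main values were log2 of the processed signal minus each array's 75th percentile, which was 191 on WT 1, 144 on WT 2, 292 on knockout 1 and 160 on knockout 2. Control spots and spots with outlier flags (35 to 73 per array) were left out, and replicate spots of a probe were averaged. A probe was tested when it was well above background on both arrays of at least 1 group, which left 24183 of 41174 probes. The files give an accession per probe and no gene symbol. Accessions without their version were matched to NCBI RefSeq genes (assembly GRCm38.p6, used for names and for which genes neighbour each other), which named 27816 probes from 18952 genes and left 13358 unnamed. A gene with several probes was represented by its brightest probe over all 4 arrays, and other tested probes of a named gene are given in the text where 1 of them differs from it by more than 0.5 on the log2 scale. Where a probe was not well above background on any array of a group, the fold is given as a lower bound. The bound sets the bright group's mean against the dim group's mean of the higher, on each array, of the lowest signal among probes well above background and the dim probe's own signal. Where it was well above background on 1 array of a group, as for Bcl11b, Ms4a1, Oas1a, Krt27, Krt10, Stmn3, Mcm2, Prdm16 and Prdm1, the fold uses the other array's reading as it stands. No list's median moved when genes not well above background on any array of a group were set at their bound. Only the milk, T and NK cell and B cell lists held such genes (1, 2 and 1), so this check could hardly move a median. Genes well above background on 1 array of a group have no bound and were left as they stood. Signal over background limits what the arrays show for dim genes, and no interval for counting error applies.

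Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, no covariate), with Benjamini-Hochberg adjustment over all tested probes and a threshold of 0.05. A count of genes with an unadjusted p under 0.05 and a fold of at least 2 was a second summary. There were 27 gene lists, each needing at least 3 measured members, tested with limma's camera at its preset correlation of 0.01 and adjusted over the lists, with camera at an estimated correlation and fry beside it. No list call held with the estimated correlation or with fry. With an estimated correlation camera rests on the fit's 2 residual degrees of freedom, where an adjusted p under 0.05 over 27 lists is hard to reach. The loss of a call there does not by itself show that correlated genes had made it. Among the called lists the estimate was below the preset for milk (-0.063), granulocyte and mast cell (-0.12) and ERBB and MAPK feedback (-0.042). It was above the preset for fibroblast and matrix (0.068), fatty acid synthesis (0.19), macrophage (0.37) and luminal epithelium (0.42). It was also above for skeletal muscle (0.55), T and NK cell (0.93) and B cell (0.99). For lists above it, the preset p is too small if the estimate holds. Camera compares a list with the other genes, and fry asks whether a list's own genes move one way. The samples, tests, gene lists, alternatives and the rule for named genes were fixed before the data were examined. By that rule the text names Stmn1, then up to 12 genes per direction with an adjusted p under 0.05 and no overlap between groups, filled to 5 from genes with an unadjusted p under 0.05 when fewer pass. It also names up to 4 passing members of each list or, where none passes, the 2 with the largest fold, and always Erbb2, Prlr, Cdkn1b, Csn2, Mki67, Krt8, Krt14 and Adipoq. The result for 1 gene that the rule names is not reported here. Csn1s1, Wap and Folr1 were named after their values were seen.

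The fit was tested on simulated data for the comparison of knockout with wild type, with changes added to 200 of 24183 probes. It called 0 of 67 probes changed by 1 on the log2 scale, 3 of 67 changed by 2 and 57 of 66 changed by 4, with 3 of 23983 unchanged probes called. So in this simulation the test found most changes of 4 on the log2 scale and missed most changes of 2. That rate depends on how many probes were changed, because the adjustment is stricter when fewer change. In the real data Csn1s2a, at -4.87, had a limma adjusted p of 0.935. Camera with its preset correlation called 100% of simulated lists of 15 genes raised by 1, 3% of unchanged lists and 72% of lists without a group change whose genes shared a factor per array of SD 0.5.

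The alternatives were quantile normalization, median scaling, the authors' deposited log2 table, normexp background correction (offset 50), no filter on dim probes, a filter on all 4 arrays, an intensity trend with and without a robust prior, the replicate number as a block, leaving out each array, the mean of a gene's probes, array weights, the other list tests and a threshold of 0.1. The files hold no mean spot signal, so normexp used the median spot signal.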

Results

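Gene expression was measured in mammary glands of 13-week-old female mice that carry Δ16HER2, a splice form of the human HER2 receptor that drives mammary tumours, before tumours had appeared. The series labels 2 arrays wild type for the stathmin gene (WT 1 and WT 2) and 2 arrays stathmin knockout (knockout 1 and knockout 2). Stathmin, encoded by Stmn1, binds tubulin and destabilises microtubules. The comparison asks which genes of the transgenic gland differ in expression when stathmin is missing. Each array was hybridised with Cy3-labelled RNA from 1 sample, and the share of probe spots well above background was 63.3% on WT 1, 54.7% on WT 2, 60.4% on knockout 1 and 66.2% on knockout 2. No spot was saturated, and Pearson correlations across probes between arrays ran from 0.963 to 0.975. With 2 arrays per group, their number limits the precision of every value below. The labels describe separate samples without saying that each came from a separate animal, so the tests measure only the spread between these samples. Levels are log2 signals relative to each array's 75th percentile, and fold changes are knockout minus wild type on that scale.

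The targeted gene came first. The brighter of the 2 Stmn1 probes (NM_019641) had processed signals of 9222 on WT 1 and 1740 on WT 2, against 6865 on knockout 1 and 1621 on knockout 2. It was well above background on all 4 arrays, and its log2 fold change of -0.64 ± 0.76 (SE, n = 2 per group, adjusted p = 0.938) was smaller than the spread within either group. The fold changed sign to 0.36 without WT 1 and was -1.64 without WT 2. The dimmer Stmn1 probe gave signals of 87.6 and 13.8 on the wild-type arrays and 5.57 and 4.84 on the knockout arrays. It was well above background on 1 of the 2 wild-type arrays and on neither knockout array, and it was at least 4.88-fold higher on the wild-type arrays. It failed the filter on dim probes, and without that filter its adjusted p was 0.910. The probes thus disagreed, and the sources used here do not give their position relative to the deleted part. The brighter probe therefore does not check the labels, and the arrays are called here by the genotype they were labelled with.

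**Figure D1:**
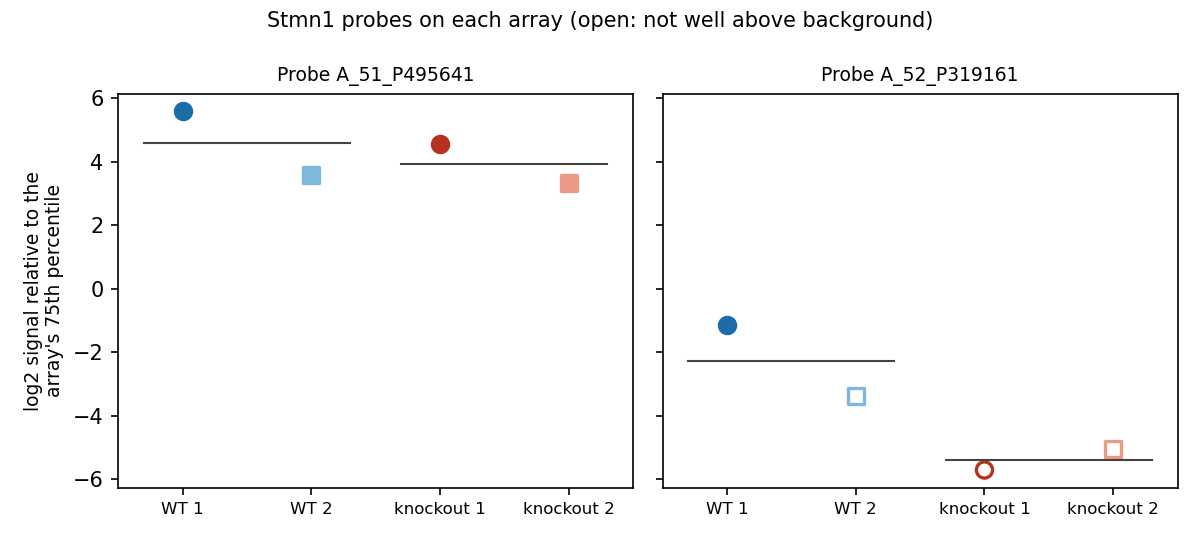
Log2 signal of the 2 Stmn1 probes relative to each array's 75th percentile, 1 point per array, with open points not well above background and lines at the group means. The brighter probe read 5.59 and 3.59 on the wild-type arrays and 4.56 and 3.34 on the knockout arrays, and the dimmer probe read -1.13 and -3.39 against -5.71 and -5.05.

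Milk genes were the group that stood lowest on the arrays labelled knockout. All 14 measured genes of the milk protein and lactation list, of 19 listed, had a negative fold change, with a median of -1.34 and a mean of -1.68 ± 1.41 (SD over genes). The caseins Csn1s2a, Csn2 and Csn1s1, the main milk proteins, had log2 fold changes of -4.87 ± 0.63, -3.88 ± 0.69 and -3.31 ± 0.84 (SE). Csn2 read 5.28 and 3.26 on the wild-type arrays and 0.10 and 0.67 on the knockout arrays. Wap, the whey acidic protein gene, was not well above background on either knockout array and was at least 4.24-fold lower there, and the folate receptor gene Folr1 had a log2 fold change of -1.68 ± 0.24. For 8 of the 14 genes both knockout arrays lay below both wild-type arrays. No member passed the test over all genes, and these 5 passed when adjusted over the list alone. Limma's camera test with its preset correlation called the list lower (adjusted p = 5.13e-09). The call was lost with an estimated correlation (adjusted p = 0.570, unadjusted p = 0.0211), and fry gave an adjusted p of 0.140. The estimated correlation was -0.063, below the preset 0.01, so correlation among these genes is not what removed the call. Leaving out 1 array at a time kept the median between -1.82 and -1.0003.

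**Figure D2:**
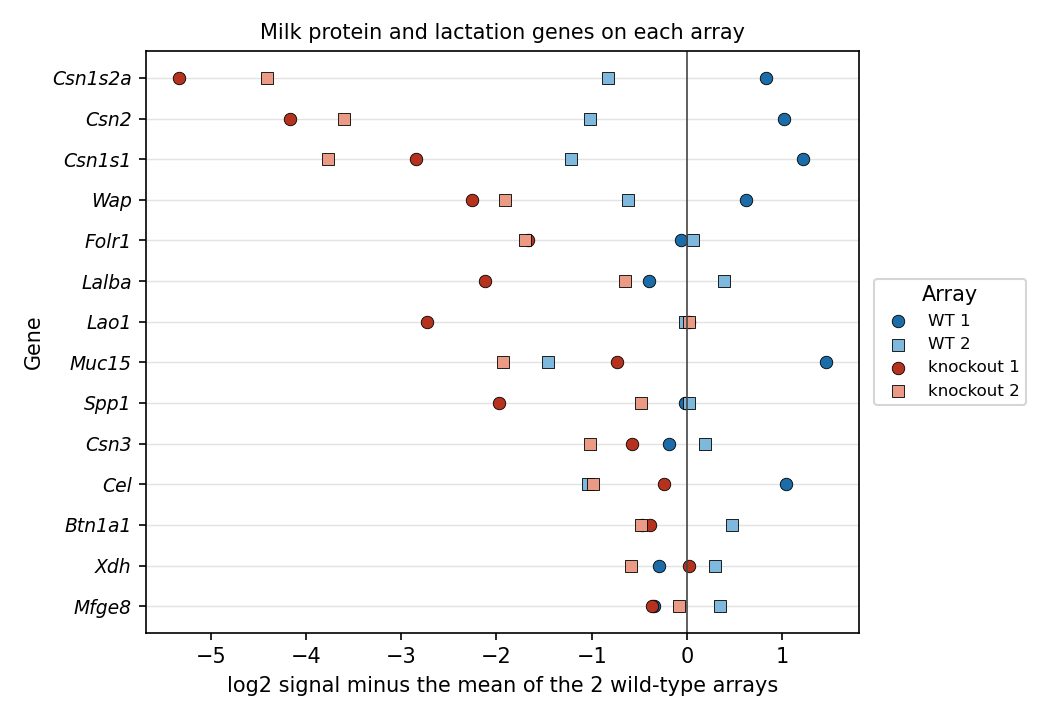
Log2 signal of the 14 measured milk protein and lactation genes on each array, minus the mean of the 2 wild-type arrays, with genes ordered by fold change. Both knockout arrays lie below both wild-type arrays for 8 genes, and the largest differences are those of Csn1s2a (-4.87), Csn2 (-3.88) and Csn1s1 (-3.31).

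Across all genes, none differed between the groups at an adjusted p under 0.05. Limma tested 24183 probes, which included 13234 named genes, and the smallest adjusted p was 0.933. At an unadjusted p under 0.05 there were 468 genes, 151 higher and 317 lower on the knockout arrays, where chance alone gives 661.7. Of these, 44 were at least 2-fold higher and 144 at least 2-fold lower. Higher genes made up 23.4% of these 2-fold genes, but 37.6% after quantile normalization and 68.1% after median scaling, which moved the median of all genes to 0.19. They made up 51.7% without knockout 1 and 13.1% without knockout 2. The direction of the majority therefore depends on the scaling and on single arrays, and fold changes are relative to each array's 75th percentile. Leaving out 1 array at a time gave 72 to 343 genes higher and 205 to 479 lower. Both knockout arrays lay above both wild-type arrays for 17.7% of genes and below them for 17.8%, against 16.7% by chance in each direction.

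The largest log2 fold changes with an unadjusted p under 0.05 and no overlap between groups did not pass adjustment either (adjusted p from 0.933 to 0.935). On the lower side these were Scrg1 at -5.52 ± 0.80 (SE), Csn1s2a, the secretoglobin Scgb2b27 at -4.29 ± 0.83 (-2.96 on its second probe), Csn2 and the noradrenaline transporter Slc6a2. Slc6a2 was not well above background on the knockout arrays and was at least 3.98-fold lower there. Scrg1 and the brighter Scgb2b27 probe were each well above background on 1 of the 2 knockout arrays. On the higher side stood Trnau1ap, a factor of selenocysteine tRNA, with a log2 fold change of 2.18 ± 0.25, though a second probe of that gene gave 0.02. Angptl8, an insulin-induced regulator of lipoprotein lipase, had 1.84 ± 0.37, or 0.82 on its second probe, and the ubiquitin ligase gene Znrf2, well above background on 1 of the 2 wild-type arrays, had 1.80 ± 0.55. The cannabinoid receptor gene Cnr2 and the nicotinic receptor gene Chrnb2 were not well above background on the wild-type arrays and were at least 3.62-fold and 2.45-fold higher on the knockout arrays. Cnr2, which lymphocytes express, read -3.72 on knockout 1 and -0.55 on knockout 2. Chrnb2 read -3.59 and -1.81 on the same arrays, so both were higher on knockout 2 than on knockout 1. Trnau1ap and Cnr2 are both among the 50 nearest measured genes on each side of Stmn1.

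Other mammary epithelial lists had smaller fold changes than the milk genes. The luminal epithelium list had a median of -0.46 with 16 of 18 measured genes negative, and camera called it lower (adjusted p = 0.000336, or 0.807 with an estimated correlation). The call was lost without knockout 2 (median -0.16, adjusted p = 0.683), and the median was -0.94 without knockout 1. Krt8, a keratin of luminal cells, had -0.36 ± 0.30 (SE), the epithelial transcription factor gene Ehf had -1.38 ± 0.74 and the protease gene Prss8 had -1.03 ± 0.31. Luminal progenitor genes had a median of -0.36 over 8 genes (camera adjusted p = 0.0616). Of these, Gabrp, a GABA receptor subunit gene, had -1.29 ± 0.28 and passed when adjusted over the list alone, and the lactoferrin gene Ltf had 0.94 ± 0.99. Hormone-sensing luminal genes had a median of -0.24 over 15 genes (adjusted p = 0.0809), with the luminal regulator Gata3 at -0.89 ± 0.28 and the oestrogen target Greb1 at -0.62 ± 0.39. With 1 array left out, the median ran from -0.58 to -0.20 for luminal progenitor genes and from -0.54 to -0.11 for hormone-sensing genes. Basal myoepithelial genes had a median of -0.26 over 14 genes (adjusted p = 0.177). In that list Krt14 had -0.35 ± 0.54, Cdh3 had -0.49 ± 0.32 and the smooth muscle myosin gene Myh11 had -0.48 ± 0.24.

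Genes of the receptor pathways gave a mixed picture. The ERBB family and MAPK feedback list had a median of -0.34 with 15 of 19 genes negative, and camera called it lower (adjusted p = 0.00676, or 0.706 with an estimated correlation). The call was lost without WT 2 (median -0.27) and without knockout 2 (median -0.41). Its members with the largest folds were the ETS factor gene Etv1, a target of MAPK signalling, at -1.64 ± 0.36 (SE) and Phlda1 at -0.85 ± 0.47. The probe annotated to mouse Erbb2 had -0.34 ± 0.29, and whether it also reads the human transgene was not tested. The prolactin and STAT5 signalling list was not called (median -0.03 over 15 genes, adjusted p = 0.791). Within it the prolactin receptor gene Prlr had -0.07 ± 0.41, the alveolar transcription factor gene Elf5 had -0.88 ± 0.51 and the connexin gene Gjb2 had -1.38 ± 1.21. Cdkn1b, which encodes the cyclin-dependent kinase inhibitor p27, had -0.42 ± 0.24. Stathmin relatives, tubulins and microtubule regulators had a median of 0.07 over 26 genes (adjusted p = 0.844), with Kif2c at -0.87 ± 0.35 and Stmn3 at 0.56 ± 0.25.

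Proliferation genes did not separate the groups but differed between the arrays of each. The median of 39 genes was -0.07 (adjusted p = 0.844). The list's mean level, relative to its mean over the 4 arrays, was 0.92 on WT 1, -0.92 on WT 2, 0.53 on knockout 1 and -0.53 on knockout 2. Mki67, a marker of dividing cells, read 2.80 and 0.49 on the wild-type arrays and 2.24 and 0.61 on the knockout arrays, a log2 fold change of -0.22 ± 0.90 (SE). The nucleotide synthesis gene Tk1 had 0.89 ± 0.78 and the replication licensing gene Mcm2 had -0.89 ± 0.77. The brighter Stmn1 probe was also higher on WT 1 than on WT 2 and higher on knockout 1 than on knockout 2, by 3.999-fold and 2.33-fold.

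Fatty acid synthesis was the one metabolic list called higher. Of its 16 genes 12 had positive fold changes and for 9 both knockout arrays lay above both wild-type arrays, with a median of 0.48 (camera adjusted p = 0.00028, or 0.778 with an estimated correlation). The median was 0.28 without WT 2. The mitochondrial citrate carrier gene Slc25a1 had 1.16 ± 0.28 (SE), and Acss2, which makes acetyl-CoA from acetate, had 1.06 ± 0.48, or 2.59 on its second probe. White adipocyte genes were not called (median 0.13 over 18 genes, adjusted p = 0.429), with Adipoq at -0.27 ± 0.30, Agpat2 at 0.71 ± 0.25 and Lep at 0.57 ± 0.53. Brown adipocyte genes had a median of 0.00 over 13 genes (adjusted p = 0.862), with Prdm16 at 1.66 ± 0.42 and Dio2 at -0.69 ± 0.46. Oxidative phosphorylation and citric acid cycle genes had a median of -0.08 over 29 genes (adjusted p = 0.844), with Cox6c at -0.90 ± 0.30 and Mdh2 at 0.77 ± 0.73.

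Lymphocyte genes were high on 1 array, knockout 2. The B cell list read -0.85 and -0.96 on the wild-type arrays, -1.69 on knockout 1 and 3.51 on knockout 2, and the T and NK cell list read -0.61, -0.77, -0.92 and 2.30. Camera called both lists higher, with medians of 2.16 over 7 genes (adjusted p = 0.0353) and 1.39 over 17 genes (adjusted p = 0.00634), and neither with an estimated correlation (adjusted p = 0.825 for each). Without knockout 2 the B cell list was called lower (median -0.75, adjusted p = 0.0065) and the T and NK call was lost (median -0.18, adjusted p = 0.102). Without knockout 1 the medians were 4.92 and 3.11. The B cell call was also lost without WT 2. The B cell surface gene Ms4a1 read -3.75, -3.57, -5.12 and 3.26 across the 4 arrays in the same order. Spib, not well above background on the wild-type arrays, read -3.95, -4.50, -4.09 and 0.87, so the knockout mean was at least 4.78-fold higher through knockout 2 alone. Cd3d and Bcl11b had log2 fold changes of 2.79 ± 1.54 (SE) and 3.1 ± 1.44. Cd3d read -2.95, -2.58, -2.44 and 2.49 across the arrays in that order, so most of its fold came from knockout 2. Plasma cell genes had a median of 0.01 over 7 genes (adjusted p = 0.878), with Mzb1 at 1.88 ± 1.17 and Prdm1 at -0.40 ± 0.26. Mzb1 read -2.91, -3.33, -3.09 and 0.61, so its fold also came from knockout 2.

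**Figure D3:**
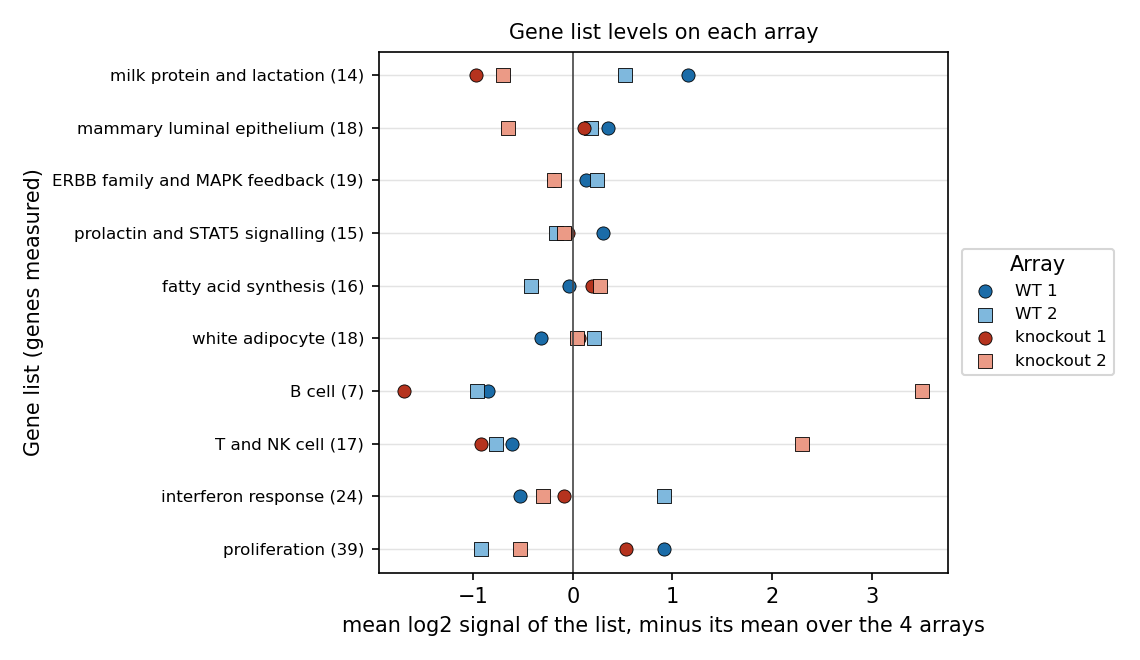
Mean log2 signal of 10 gene lists on each array, minus the list's mean over the 4 arrays, with the number of measured genes in brackets. The milk list lies below 0 on both knockout arrays (-0.97 and -0.70), and the B cell list lies at 3.51 on knockout 2 and below 0 on the other 3 arrays.

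Myeloid and stromal lists were lower by smaller amounts. The granulocyte and mast cell list had a median of -0.65 over 8 genes (camera adjusted p = 0.000776, or 0.706 with an estimated correlation), and the call was lost without WT 2. Its mast cell protease genes Cpa3 and Tpsb2, at -1.03 ± 0.25 (SE) and -0.95 ± 0.26, passed when adjusted over the list alone. Macrophage genes had a median of -0.18 over 21 genes (adjusted p = 0.0068, or 0.825 with an estimated correlation), with the scavenger receptor Cd163 at -1.15 ± 0.25 and the lectin Clec10a at -1.07 ± 0.32. The macrophage call was lost without WT 2 (median -0.000275) and without knockout 1 (-0.21), and the median turned to 0.01 under median scaling. Fibroblast and matrix genes had a median of -0.27 over 27 genes (adjusted p = 0.00154, or 0.778 with an estimated correlation), with Fn1 at -1.01 ± 0.24 (-0.33 and -0.55 on its other probes) and Col3a1 at -0.70 ± 0.24. That call was lost without knockout 2, at a median of -0.14, and the median was -0.17 without WT 2 and -0.42 without knockout 1. Skeletal muscle genes had a median of -0.33 over 21 genes (adjusted p = 0.00446, or 0.825 with an estimated correlation), with Pvalb at -1.66 ± 0.58 and Ryr1 at -0.81 ± 0.36, or 0.16 on its second probe. That median was 0.01 without knockout 1, -0.54 without knockout 2 and -0.23 without WT 1, and the call held in the second case alone of these 3.

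No other list was called in the main comparison. Interferon response genes had a median of -0.40 over 24 genes (adjusted p = 0.374), with Oas1a at -2.29 ± 1.33 (SE) and Oasl2 at -1.02 ± 0.78. Nerve and Schwann cell genes had a median of -0.16 over 11 genes (adjusted p = 0.227), with the neural crest factor Sox10, which mammary epithelium also expresses, at -1.93 ± 0.45. Endothelial genes had a median of -0.12 over 20 genes (adjusted p = 0.242), with Erg at -0.53 ± 0.27 and Cdh5 at -0.46 ± 0.25. Epidermis and hair follicle genes had a median of -0.28 over 6 genes (adjusted p = 0.501), with Krt27 at -0.51 ± 0.80 and Krt10 at -0.39 ± 0.58. The p53 targets had a median of -0.21 over 17 genes (adjusted p = 0.785), with Plk2 at -0.73 ± 0.40 and Fas at 0.45 ± 0.31. Immediate early and heat shock genes, which report on tissue handling, had a median of -0.02 over 22 genes (adjusted p = 0.923), with Atf3 at 1.12 ± 0.29 and Hspa1a at 1.04 ± 0.54. Red blood cell genes had a median of 0.08 over 4 genes (adjusted p = 0.971), with Klf1 at -0.48 ± 0.28 and Alas2 at 0.34 ± 0.43. For the proliferation, stathmin, brown adipocyte, immediate early and red blood cell lists the median, the mean and the test's direction did not all have the same sign.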

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

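The results were recomputed under 18 alternatives, all planned, and leaving out an array assumes that the lone array of a group varies like the others. Scaling by the spike-in probes was planned and not run, because 0 of the 10 E1A probes were well above background on all 4 arrays. The count of genes past an adjusted p of 0.05 stayed at 0 in both directions except under median scaling, where 3 genes were lower (Csn1s2a, Scrg1 and Slc6a2), and the cause was not tested. A threshold of 0.1 also gave 0. Of 745 fold changes of named genes under alternatives that kept every array, 741 kept direction and side of the threshold, and those 3 passed it. Prlr reversed, to 0.13 under median scaling, which moved the median of all genes to 0.19. The labels do not say whether arrays of the same replicate number were linked. Over probes, the difference WT 1 minus WT 2 correlated with knockout 1 minus knockout 2 at r = 0.0648 (rho = 0.0179). A low correlation over all probes cannot exclude a link, and proliferation genes followed the replicate number in both groups. With the replicate block, 59 genes were at least 2-fold higher and 180 lower, with 3 lists called higher and 8 lower. Signal over background limits dim genes: without the filter on dim probes, 18951 named genes were tested in place of 13234.

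The count of genes at least 2-fold higher was 44 in the main comparison, 74 after quantile normalization, 75 in the authors' deposited table, 213 after median scaling, 25 after normexp and 27 with the filter on all 4 arrays. The count at least 2-fold lower was 144, with 57 after normexp and 379 without the filter on dim probes, where more dim genes were tested. Of the 188 genes in both counts, 161 were shared in the same direction after quantile normalization, 134 after median scaling and 59 after normexp. Leaving out 1 array gave 72 to 343 genes higher and 205 to 479 lower, and the Stmn1 fold ran from -1.64 to 0.36. The lists called higher numbered 3 and those called lower 7. With the filter on all 4 arrays 1 list was called higher, and without the filter on dim probes 4 were called lower. With 1 array left out, 2 to 5 were called higher. Camera with an estimated correlation called 0 in each direction, and so did fry, so every call was lost in both with the medians as they stood: milk -1.34, fatty acid synthesis 0.48, luminal epithelium -0.46, granulocyte and mast cell -0.65, fibroblast and matrix -0.27, skeletal muscle -0.33, T and NK cell 1.39, ERBB and MAPK feedback -0.34, macrophage -0.18 and B cell 2.16. For the milk list these adjusted p were 0.570 and 0.140, and over its other alternatives the adjusted p ran from 4.23e-27 to 2.64e-06.

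Without the filter on dim probes the calls of the fibroblast (-0.27), skeletal muscle (-0.33) and macrophage (-0.12) lists were lost, and with the filter on all 4 arrays those of the T and NK cell (1.096) and B cell (1.95) lists. The macrophage median reversed to 0.013 under median scaling. With 1 array left out, the medians ran from -0.94 to -0.16 for luminal epithelium, -0.87 to -0.54 for granulocyte and mast cell, -0.42 to -0.14 for fibroblast and matrix, -0.54 to 0.0093 for skeletal muscle, -0.18 to 3.11 for T and NK cell, -0.42 to -0.27 for ERBB and MAPK feedback, -0.48 to -0.000275 for macrophage and -0.75 to 4.92 for B cell. The milk and fatty acid lists were called with each array left out. Without knockout 2 the B cell list was called lower.

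Lists not called in the main comparison were called by camera with its preset correlation under some of the other 15 alternatives: luminal progenitor under 5, hormone-sensing luminal and proliferation under 4 each, interferon response under 3, basal myoepithelium, nerve and Schwann cell, and epidermis under 2 each, and white adipocyte under 1. The proliferation calls all came with 1 array left out (lowest adjusted p = 1.45e-13), higher without WT 1 or knockout 2 and lower without WT 2 or knockout 1. Interferon response genes were called lower without WT 1 (adjusted p = 1.48e-12) and higher without WT 2.

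Lists that were not called reversed as follows, and the cause was not tested beyond the shift that median scaling itself makes. Under median scaling the medians were 0.036 for nerve and Schwann cell, 0.078 for endothelium, 0.16 for prolactin and STAT5, 0.11 for oxidative phosphorylation, 0.12 for proliferation and 0.17 for immediate early genes. After normexp they were 0.021 for prolactin and STAT5, 0.026 for oxidative phosphorylation, -0.069 for brown adipocyte, -0.10 for plasma cell and, as gene list median log2 fold change: immediate early and heat shock, 0.000267. As gene list median log2 fold change: brown adipocyte, the value was -0.024 after quantile normalization and in the authors' deposited table, -0.10 without the filter on dim probes and -0.20 with the filter on all 4 arrays. Without the filter on dim probes, plasma cell genes were at -0.12 and red blood cell genes at -0.073. With 1 array left out, the medians ran from -0.46 to 0.040 for basal myoepithelium, -0.22 to 0.020 for nerve and Schwann cell, -1.07 to 0.42 for interferon response, -0.17 to 0.45 for white adipocyte, -1.05 to 0.18 for epidermis, -0.22 to 0.16 for p53 targets, -0.17 to 0.10 for oxidative phosphorylation, -0.10 to 0.15 for stathmin relatives and tubulins, -1.06 to 0.93 for proliferation, -0.36 to 0.016 for brown adipocyte, -0.14 to 0.24 for plasma cell, -0.076 to 0.081 for immediate early genes and -0.34 to 0.44 for red blood cell.

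Of 276 fold changes of named genes with 1 array left out, 259 kept their direction and 17 reversed, and none passed the threshold. Their ranges were -1.46 to 6.92 for Ms4a1, -0.59 to 2.47 for Ltf, -2.16 to 0.12 for Oasl2, -0.057 to 1.21 for Lep, -1.73 to 0.72 for Krt27, -1.25 to 0.48 for Krt10, -3.07 to 0.32 for Gjb2, -0.32 to 1.85 for Mdh2, -0.13 to 1.91 for Tk1, -1.84 to 0.062 for Mcm2, -0.22 to 0.90 for Alas2, -0.54 to 0.40 for Prlr, -1.37 to 0.93 for Mki67, -1.08 to 0.38 for Krt14 and -0.56 to 0.014 for Adipoq.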

Other observations

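All tests in this part were chosen after the results they bear on had been seen. Several gene groups differed between arrays of 1 group rather than between genotypes. The interferon response list stood highest on WT 2 (0.92, against -0.53 on WT 1, -0.09 on knockout 1 and -0.29 on knockout 2), and Oasl2, an antiviral gene, read -0.35, 1.93, 0.14 and -0.59 across WT 1, WT 2, knockout 1 and knockout 2. Proliferation genes were high on WT 1 and knockout 1. Calca, the calcitonin gene and a member of the hormone-sensing luminal list, followed that order more steeply, at 6.53, 0.49, 5.60 and 0.52, and was chosen after its values were seen. Epidermis and hair follicle genes were highest on WT 1 (1.33) and lowest on WT 2 (-1.09). With 4 arrays no correlation between these groups was computed. The other 2 ways to split the 4 arrays into pairs gave 322 and 193 genes at least 2-fold different at an unadjusted p under 0.05, against 188 for the real split, and 8 and 12 lists called by camera with its preset correlation, against 10. In the split of WT 1 and knockout 1 against WT 2 and knockout 2, the list with the smallest p was the proliferation list.

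Milk genes were lower on both knockout arrays, and dilution by lymphoid tissue on knockout 2 is a possible explanation. The milk median without that array, which was -1.82, argues against such dilution as the whole cause. That median rests on knockout 1, so it cannot test whether dilution lowered the milk genes on knockout 2. On knockout 1, the milk list lay further below the wild-type arrays than the luminal epithelium list did. The difference of means was -1.66 (95% interval over resampled genes -2.51 to -0.89). Such an interval takes genes as independent and holds no spread between samples. For that 1 array the values argue against a lower epithelial share as the whole cause. On knockout 2 the difference of means was -0.63 (-1.43 to 0.09) and the medians lay close together. This leaves a lower epithelial share on knockout 2 open, whether through dilution by lymphoid tissue or not. The stage of the reproductive cycle or an earlier pregnancy cannot be told apart from genotype here, because the labels do not give it. Single milk genes differed between the 2 wild-type arrays by a median absolute 0.87, with 7 of 14 higher on WT 1. The median absolute fold between groups was 1.34. That fold compares means of 2 arrays, while the wild-type difference compares single arrays, which vary more. The 2 values are therefore not like for like. With 3 splits of the arrays a share under 0.05 cannot be reached, and the real split, the 1 with the largest absolute milk median, gave 1.34 where the highest other gave 0.69. Slide position, the share of secretory cells within the epithelium, and genotype itself stay open and untested.

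Lymphocyte genes were high on knockout 2 alone, and lymph node tissue in that sample is a candidate explanation. A list of 14 markers of lymph node stroma, follicles and lymphocytes was written before the markers' own values were looked at, and none of its 10 measured genes is in the lists used above. All 10 were higher on knockout 2 than on each of the other 3 arrays, against 25.6% of all genes (exact binomial one-sided p = 1.21e-06, with genes taken as independent). The node chemokine genes Ccl19, Ccl21a and Cxcl13 read 4.73, 3.42 and 2.46 on knockout 2, and at most -1.04, -1.51 and -0.13 on the others, so lymphocytes without node stroma would be a poorer match, though a lymphoid aggregate within the gland would read alike. A rise shared by both knockout arrays is argued against for the B cell list by its direction on knockout 1. There it differed from the wild-type mean by -0.78 (95% interval over resampled genes -1.35 to -0.21). This interval and the next resample correlated genes of 1 array (estimated correlation 0.99 and 0.93), so neither measures the spread between samples. For the T and NK cell list the difference on knockout 1 was -0.23 (-0.53 to 0.09), against 2.98 on knockout 2, which leaves a small shared effect open there, and an effect in 1 animal stays untested.

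Several genes that neighbour Stmn1 were among the 2-fold genes, and alleles of another mouse strain carried along with the targeted locus could bring this about. Among the 100 nearest measured genes (50 on each side), 6 were at least 2-fold different at an unadjusted p under 0.05, and a share of 0.0118 of such windows across the genome held at least as many, with 8 the highest. Trnau1ap and Cnr2, seen near Stmn1 beforehand, prompted this count, and without them the share was 0.0517 (0.0368 for 25 genes on each side and 0.0588 for 100), so the count does not decide whether neighbours differ more often than other genes. Under the other 2 splits of the arrays the window of 50 genes on each side held 2 and 1 such genes, and that of 100 on each side 6 and 2, against 9. By labelled genotype the 6 genes were Trnau1ap (2.18, or 0.02 on its second probe), Trnp1 (1.39), Gpatch3 (1.24), Rab42 (at least 2.07-fold), Cnr2 (at least 3.62-fold) and Pafah2 (-1.15), the last with no measured gene between it and Stmn1. Lymphoid tissue on knockout 2 is argued against as the whole cause for 4 of the 6, which kept a 2-fold difference on knockout 1 alone. It stays open for Pafah2 (-0.83 on knockout 1) and for Cnr2. Against the wild-type floor Cnr2 read 0.27 on knockout 1 and 3.44 on knockout 2. The threshold on unadjusted p favours genes whose knockout arrays agree, so the count of 4 was partly set by the selection. Alleles of another strain, sequence differences under the probes, a direct effect of the targeting, and chance stay open.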
